A study of Mus musculus with 30 samples.

How the data were processed

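Peritoneal macrophages of 30 mice were profiled on an nCounter mouse inflammation panel. Per the labels' protocols, LPS at 2 mg/kg or an equal volume of PBS was injected intraperitoneally, cells were harvested after 6 h, and total RNA with an integrity number of at least 7.0 was adjusted to 20 ng/µl. The values deposited by the authors are a signal per gene and sample. How they were computed from the counts, and with which software, is not given in the sources used here, so the steps were read from the values. The deposited signal lay on whole steps with an offset in each lane, as the removal of a background leaves them, and had a floor of 1. The gene rows were then scaled so that the geometric mean of Cltc and Gapdh was 8147.9 in each of the 30 lanes. The other 4 reference genes (Gusb, Hprt, Pgk1 and Tubb5) were not held equal. The deposited signal came in 2 tables of 268 and 266 rows with equal values in all 266 shared rows, and the larger was used. No column lacked a sample.

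Groups came from the labels and the replicate numbers from the sample titles. Depth was estimated from the low values of each lane, which lie on whole steps (100.0% of them within a tolerance of 0.1 of a step). These estimates served for depth and for the comparison of sample pairs by a chi-square test of counts, and not for testing genes. Reversa samples 55 and 56 were averaged on the basis of that test (p = 0.014, chi-square 1.24 per gene, median of the 75 pairs within groups 120.73). The labels describe separate mice in each group. The run and lane of each sample were read from the column names.

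The plan, fixed before the data were examined, foresaw a count test. Because the values are not counts, the planned fallback was used, limma 3.58.1 in R 4.3.3 on log2(signal + 1). Fold changes are on that scale, which understates the change of low genes. Genes with signal above 20 in at least 6 samples were tested, 202 of the 248 target genes, and the 6 reference genes were not tested. All 29 samples entered 1 fit with a mean per group, lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All tests were two-sided. Principal components were taken over the LPS samples from the tested genes, centred and not scaled. Where most samples of one group were under 20, the fold is a bound, "at least N-fold", from geometric means with each value of that group set to no less than 20, and no fold is given where both groups were mostly under 20.

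The named genes followed a rule fixed at the same time. It takes Ptgs1 and Ptgs2 everywhere, the 10 largest and 10 smallest log2 changes among genes past the threshold in each comparison with the control, up to 4 genes of smallest p per gene list, and the 5 smallest p-values between genotypes or where fewer than 5 genes passed. Other genes named, such as Il6, Il1b, Alox15 and Mrc1 in Reversa and those past the test between genotypes, were chosen after their values were seen. Gene lists, 18 in number, were written beforehand, and 16 had at least 3 tested genes. They were tested with fry and with camera (preset correlation 0.01, and an estimated one). Gene symbols of the panel were matched to the GRCm38.p6 gene table, where 7 of 254 stood under another name, such as Chi3l3 under Chil3, and the panel names are printed.

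Levels of Ptgs1 and Ptgs2 were tested by exact permutation of the samples. The fits were tested on simulated data drawn from the fitted means and spreads of the 202 genes, with 20 simulations per comparison. For Reversa 96.2% of genes changed 4-fold, 70.8% of those changed 2-fold and 40.0% of those changed 1.5-fold were called, and 2.7% of calls were false. For COX-1>COX-2 the shares were 98.1%, 78.8% and 40.8%, with 4.7% of calls false. With no gene changed the mean number of calls was 0.10 in both. Fry detected 100.0% of 10-gene lists shifted 1.5-fold and 5.0% of unshifted ones in both. The simulated noise was independent between genes, while real genes correlate, with an estimated 0.48 within the neutrophil-attracting chemokines. The simulated shares therefore do not cover errors that arise from correlated genes. Each simulation with changed genes also altered more of them at once than passed in either comparison. This loosens the adjusted threshold, so a gene changed alone would be called less often.

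Alternatives were other scalings (total signal, all 6 reference genes, 4 reference genes without Gapdh and Pgk1, and the median of all genes), no filter, a filter on all samples, a pseudocount of 10, only the groups compared, each sample left out and the replicate number as a block. Run as a block, each run alone, Reversa 55 and 56 kept apart and a prior variance that follows the mean were added after the data were seen. Values under run 3 alone rest on a single Reversa sample, assumed to vary like the others. Planned count-based scalings and tests were not run, because they need counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for depth estimates and plots.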

Results

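RNA of mouse peritoneal macrophages was measured on an nCounter panel, which counts colour-coded probes on single RNA molecules without amplification. The panel held 248 target genes, most of them in inflammation, and 6 reference genes. There were 30 samples in 5 groups of 6 mice on the C57BL/6 strain, aged 12 to 16 weeks, each sample from a separate mouse per the labels. Wild-type mice received the vehicle (WT-LPS) or 2 mg/kg of lipopolysaccharide (WT+LPS), a component of the bacterial wall that is sensed by Tlr4, and cells were taken after 6 h. The other 3 groups also received lipopolysaccharide (LPS) and carried exchanged cyclooxygenase genes. From what is known of these lines, COX-1>COX-2 mice have the coding sequence of Ptgs1 (COX-1) in the Ptgs2 locus, COX-2>COX-1 mice have that of Ptgs2 (COX-2) in the Ptgs1 locus, and Reversa mice have both exchanges. Both genes encode enzymes of the first step of prostanoid synthesis, Ptgs1 in a mostly constant and Ptgs2 in an induced manner. No exchange mice received the vehicle.

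Total signal of the target and reference genes ranged from 471534 to 773828 per sample. The counts behind it, recovered from the steps between low values, ranged from 298396 to 1001821 per sample. By group they were 433592 ± 150072 in WT-LPS, 611419 ± 84640 in WT+LPS, 535782 ± 127575 in COX-1>COX-2, 585725 ± 147577 in COX-2>COX-1 and 647025 ± 239859 in Reversa (SD, n = 6 each). A single count was worth 0.646 to 1.937 signal units, so values under 20, the level that 1 of 240 negative control values passed, were treated as not above background. The control rows are not scaled as the gene rows are, so a signal of 20 stands for different numbers of counts in the lanes. The Reversa samples numbered 55 and 56 differed by hardly more than counting noise, with a chi-square of 1.24 per gene against 24.25 in the next closest of the 75 pairs within a group. Their mean was counted as 1 sample, which leaves 5 Reversa samples and 29 samples in each fit. The samples were measured in 3 runs that each held 2 lanes of every group. Each group had the same lanes in every run. They were 1 and 2 for WT-LPS, 3 and 4 for WT+LPS, 5 and 6 for COX-2>COX-1, 7 and 8 for COX-1>COX-2, and 9 and 10 for Reversa. An effect of lane position therefore cannot be told apart from one of treatment or genotype, and a run block does not remove it.

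The levels of the exchanged genes came first, because they check the genotype labels. In wild-type cells Ptgs1 signal was 2652 ± 364 after vehicle and 238 ± 71.3 after LPS (SD, n = 6 each), a change of -3.52 ± 0.31 (SE) on the log2 scale. Ptgs2 signal was under 20 in 5 of the 6 vehicle samples and 4909.9 ± 1135 after LPS, at least 224-fold higher. In COX-1>COX-2 cells Ptgs2 signal lay between 1 and 1.76, at least 241-fold below WT+LPS. Ptgs1 signal in COX-1>COX-2 was 441 ± 84.1 (n = 6), 1.89-fold that of WT+LPS. In COX-2>COX-1 cells Ptgs1 signal lay between 1 and 5.77, at least 11.4-fold below WT+LPS, and Ptgs2 signal was 6471 ± 2273. Reversa cells had both transcripts, with Ptgs1 at 240.4 ± 171 and Ptgs2 at 292 ± 142 (n = 5), the second 18.7-fold below WT+LPS. The single exchanges thus each lacked the transcript of the replaced gene, while Reversa cells held a Ptgs2 signal of 88.0 to 487 against 3719 to 7007 in WT+LPS.

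Exact two-sided permutation tests of the mean log2 signal gave p = 0.0022 (Benjamini-Hochberg p = 0.0031 over 14 tests), the smallest value these group sizes allow, for both genes after LPS in wild-type cells, for Ptgs2 in COX-1>COX-2 and in Reversa, and for Ptgs1 in COX-2>COX-1. For Ptgs1 in COX-1>COX-2 the exact p was 0.0043 (adjusted 0.0055), while limma, which adjusts over all 202 genes tested, gave an adjusted p of 0.16. With only the groups of the comparison in the limma fit that adjusted p was 0.049. Ptgs2 in COX-2>COX-1 (exact p = 0.15) and Ptgs1 in Reversa (exact p = 0.66) did not differ from WT+LPS by more than the spread between mice. Where the probes bind is not given in the sources used here. For Ptgs1 in COX-1>COX-2 and Ptgs2 in COX-2>COX-1, native transcripts therefore cannot be told from those made at the exchanged locus. In Reversa both native genes are replaced. Each replacement alone left little signal, with Ptgs2 at 1 to 1.76 in COX-1>COX-2 and Ptgs1 at 1 to 5.77 in COX-2>COX-1. The signals of both genes in Reversa thus argue for transcripts from the exchanged loci.

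**Figure D1:**
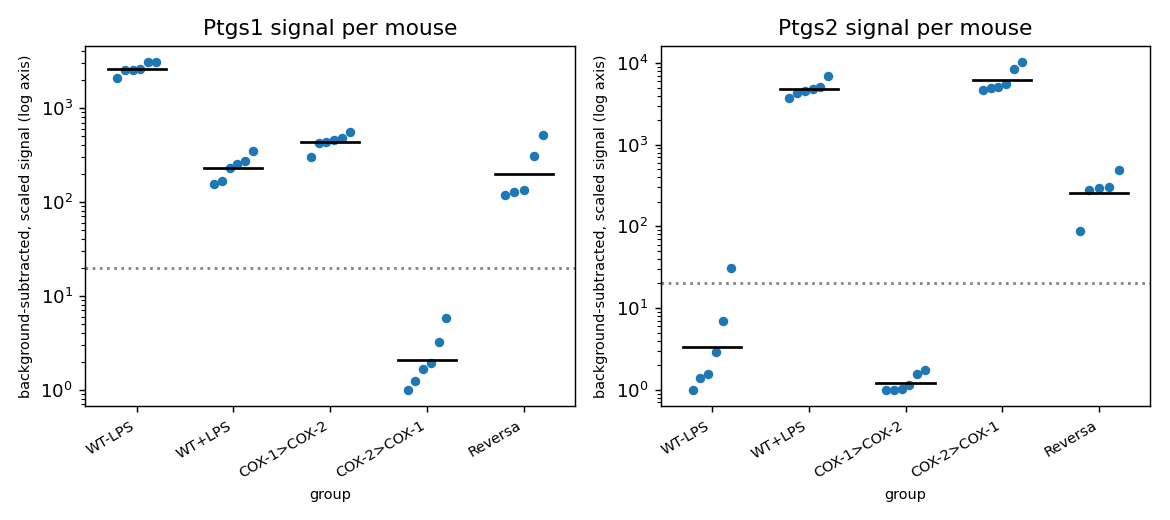
Signal of Ptgs1 (left) and Ptgs2 (right) in each sample (points; log axis), by group, with the geometric mean of each group as a bar and the background level of 20 as a dotted line. Ptgs2 lay between 1 and 1.76 in COX-1>COX-2, Ptgs1 between 1 and 5.77 in COX-2>COX-1, and Reversa samples had Ptgs2 between 88.0 and 487.

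The first comparison asked which genes of the panel LPS changes in wild-type peritoneal macrophages. Chemokines were among the genes that rose most. Cxcl10, which attracts activated T cells, went from 5.47 ± 7.34 to 49256 ± 10092 (SD, n = 6 each), at least 2424-fold. The monocyte chemokine Ccl7 rose at least 355-fold and Ccl2, another, 87.8-fold, from 184 ± 47.2 to 15893 ± 1683. Nos2, the inducible nitric oxide synthase, rose at least 305-fold, and Csf3, the growth factor of neutrophils, at least 169-fold. Among the genes that fell, Tgfb2 went from 2291 ± 592 to 10.8 ± 5.70, at least 110.2-fold, and the chemokine receptor Ccr2 fell from 3321 ± 559 to 132 ± 35.7.

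All 4 neutrophil-attracting chemokines tested were higher, among them Cxcl1 (128-fold, from 82.0 ± 31.1 to 10775 ± 4022) and Cxcl2 (68.3-fold), and Cxcl3 rose at least 352-fold. All 11 monocyte and lymphocyte chemokines were higher, with Ccl3 up 413-fold, Ccl4 at least 262-fold and Cxcl9 at least 122-fold. Of 14 pro-inflammatory cytokines 11 were higher, 1 was lower and 2 did not pass. Il1b rose 168-fold to 5232 ± 1609.7, Il1a rose 138-fold, Il6 rose at least 95.8-fold, and the lymphotoxin gene Ltb, which this list shares with the B cell markers, was the lower one, 13.1-fold below vehicle. Of 17 interferon-stimulated genes 16 were higher and 1 did not pass, with Ifit1 up 79.6-fold, Oasl1 109-fold and the transcription factor Irf7 18.7-fold. In the NF-kB list 9 of 11 genes were higher and 2 lower, with Tnfaip3, a feedback inhibitor of the pathway, up 33.8-fold to 15290.0 ± 1946 and Bcl2l1 up 4.28-fold, but the list median of 0.91 on the log2 scale went to 0.00 under equal medians of all genes. Fry's test for movement on balance in one direction gave adjusted p = 1.6e-17 for the cytokines and for the neutrophil-attracting chemokines, 6e-25 for the other chemokines, 6.5e-18 for the interferon-stimulated genes and 5.4e-13 for the NF-kB list. Camera, which sets a list against the other genes, called none of them with an estimated correlation (adjusted p = 0.33, 0.33, 0.059, 0.30 and 0.67 with an estimated correlation, in the same order).

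Of 13 eicosanoid enzymes and receptors 9 were lower, 3 higher (Ptgs2, Pla2g4a and Ptger3) and 1 did not pass (fry adjusted p = 7.6e-08, but camera adjusted p = 0.33 with an estimated correlation). Alox15, a lipoxygenase of resident peritoneal macrophages, fell 8.28-fold from 32856 ± 5507 to 4114 ± 1459, Alox5 fell 6.42-fold, and Tbxa2r, the thromboxane receptor, fell at least 3.19-fold. Of the 5 prostanoid receptors 4 were lower, including Ptger2 (5.05-fold), and Ptger3 was 3.21-fold higher (fry adjusted p = 5.4e-13, camera adjusted p = 0.30 with an estimated correlation). Of 9 macrophage markers 7 were lower and 2 did not pass (fry adjusted p = 1.4e-07, camera adjusted p = 0.33 with an estimated correlation). C1qa, a chain of complement C1q, fell 3.60-fold from 26338 ± 3743 to 7406 ± 1767, the adaptor Tyrobp fell 3.03-fold and the complement receptor C3ar1 3.83-fold.

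The remaining lists held members that went both ways. Among 19 genes of anti-inflammatory and alternative activation 8 were higher and 6 lower, with Il1rn, the interleukin-1 receptor antagonist, up at least 62.6-fold, Il10 up at least 10.8-fold and Ccl22 up 40.8-fold. Of 16 Toll-like receptors and adaptors 7 were higher and 5 lower, with Tlr3 up at least 7.93-fold, Nlrp3 10.3-fold and Myd88 3.66-fold. The 31 MAP kinase and AP-1 genes held 10 higher and 15 lower, with Jun up 4.57-fold, Mapk3 down 5.31-fold and Map2k6 down at least 6.59-fold. Of 10 complement genes 3 were higher, including factor B (Cfb, 7.99-fold) and C1s (at least 3.62-fold), and 5 were lower, including Cd55 (7.48-fold). In the MHC class II and costimulation list 2 of 4 were higher, Cd40 (3.78-fold) and Cd86 (3.60-fold), and H2-Eb1 was 2.14-fold lower. Fry's adjusted p was 0.00076 for the anti-inflammatory list, 1.2e-05 for the Toll-like receptors, 0.086 for the MAP kinases, 0.0089 for complement and 5.1e-05 for MHC class II. With an estimated correlation camera gave an adjusted p of 0.93, 0.96, 0.67, 0.67 and 0.93 for these lists. Under a rescaling to equal medians of all genes the medians of the Toll-like receptor, anti-inflammatory and MHC class II lists turned negative, at -0.71, -0.20 and -0.07. Rescaled by 4 reference genes without Gapdh and Pgk1, the medians of the MAP kinase and complement lists turned positive, at 0.25 and 0.03. The Toll-like receptor list was also negative under equal totals (-0.20).

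Markers of other cell types were measured beside these lists. Of 6 T cell and NK cell markers 2 were higher, Ifng (at least 32.9-fold, to 704 ± 293) and Fasl, and 2 were lower, Cd4 (5.74-fold) and Cd40lg. Of 3 B cell markers 1 was higher, Cd40, and 1 lower, Ltb, and the list's median of 0.49 and mean of -0.43 on the log2 scale had opposite signs (fry adjusted p = 0.28). Under equal medians of all genes the medians of the T cell and B cell lists were -0.41 and -0.42. Of 3 mesothelial and stromal markers 2 were higher, Flt1 (at least 2.38-fold) and Areg, whose signal was mostly under 20 in both groups. Of 2 neutrophil markers Cxcr2 rose at least 2.23-fold to 46.0 ± 12.4 and Mmp9 fell from 117 ± 58.2 to 40.6 ± 8.75. The mast cell and eosinophil genes Il5 and Il13 were mostly under 20 in both groups.

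In total limma called 100 genes higher and 69 lower of 202 tested (Benjamini-Hochberg adjusted p under 0.05). In 146 of the 202 genes all samples of one group lay above all of the other, where chance gives 0.216% of genes. The count was 168 with run as a block, and within runs 1, 2 and 3 it was 111, 143 and 152, while 168 of the 169 kept their sign in all 3 runs. The direction of small changes rests on the scaling, because the authors' values hold the geometric mean of Cltc and Gapdh equal in all lanes. Rescaled by 4 reference genes without Gapdh and Pgk1 the split was 120 higher and 43 lower, and rescaled to equal medians of all genes 74 higher and 105 lower. These rescalings moved the median log2 change of all genes by 0.51 and -0.91, and equal totals moved it by -0.40. The unscaled reference genes moved too. Pgk1, a glycolytic enzyme, was 4.48-fold higher after LPS (1592 ± 283 against 356 ± 75.5) and Hprt 2.14-fold higher, while Gusb was 3.04-fold and Tubb5 2.18-fold lower. Adjusted over the list alone the counts of 15 of the 16 lists were the same, and the MAP kinase list then held 9 higher and 14 lower. Camera called 6 lists with a preset correlation of 0.01 and none of the 16 with an estimated correlation (lowest adjusted p = 0.059 with an estimated correlation, for the monocyte and lymphocyte chemokines).

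**Figure D2:**
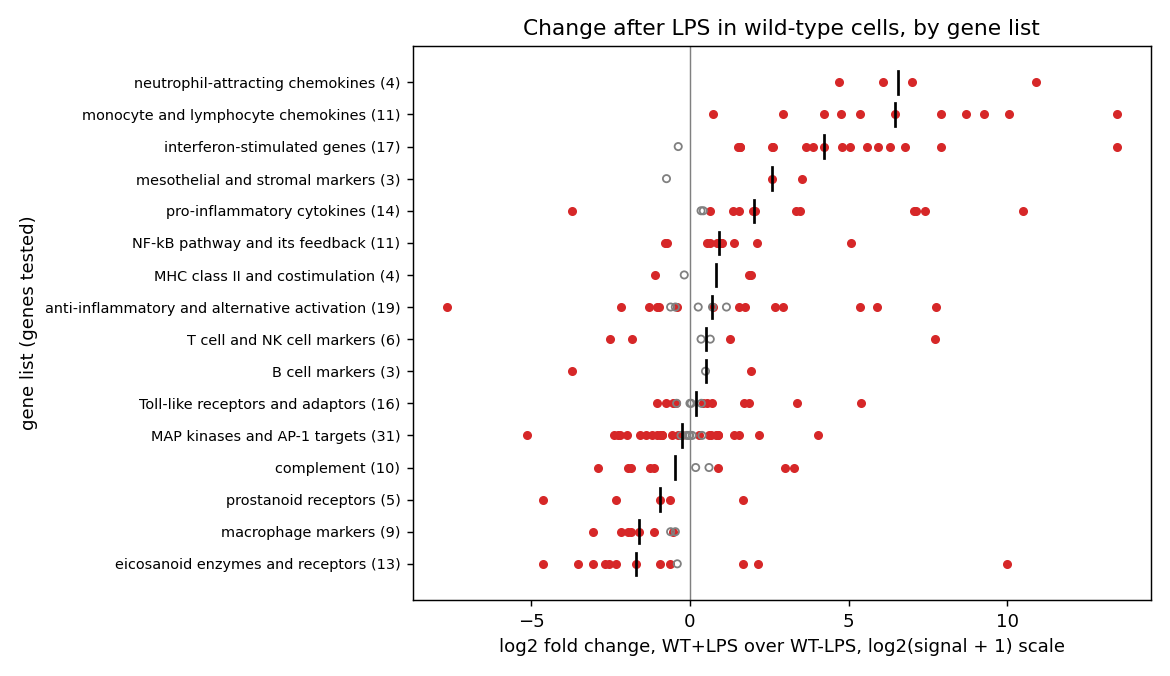
Log2 fold change of WT+LPS over WT-LPS for each tested gene, grouped by gene list (number of genes tested in brackets); filled points passed the test, open points did not, and black bars are list medians. Chemokine and interferon lists lie to the right of 0, with 11 of 11, 4 of 4 and 16 of 17 genes higher, and macrophage markers lie to the left, with 7 of 9 lower.

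The next comparisons asked what each exchange changes in LPS-treated cells, set against WT+LPS. In COX-1>COX-2 cells the inflammatory panel differed little from wild type. Besides Ptgs2, only Limk1, a kinase that acts on the actin regulator cofilin, passed the test, at 369 ± 78.0 against 233 ± 24.1 in WT+LPS (SD, n = 6 each), 1.56-fold higher, with all 6 samples above all wild-type samples (adjusted p = 0.011). Tlr8, a receptor for single-stranded RNA, was at 334 ± 198 against 628 ± 221 and Il18rap, a subunit of the interleukin-18 receptor, at 151 ± 77.9 against 267 ± 59.6, and neither passed (adjusted p = 0.14 each). The growth factor Csf2 was at 16.5 ± 7.32 against 35.7 ± 13.5 (adjusted p = 0.16) and Il13 at 19.5 ± 9.93 against 8.36 ± 6.18 (adjusted p = 0.16). Ccl5 was at 29534 ± 8474 against 42109 ± 3926 (adjusted p = 0.20).

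The count was 1 gene higher and 1 lower of 202, and 18 genes had an unadjusted p under 0.05. It stayed at 2 with run as a block, and within each of the 3 runs it was 1. Without COX-1>COX-2 sample 58 it was 1, with Limk1 at an adjusted p of 0.053, without sample 59 it was 4 and without sample 60 it was 5. None of the 14 cytokines, 11 monocyte and lymphocyte chemokines, 17 interferon-stimulated genes, 11 NF-kB genes or 31 MAP kinase genes passed. The list of eicosanoid enzymes and receptors was the only list lower on balance (fry adjusted p = 0.012). Ptgs2 was its only member to pass, and adjusted over the list alone Ptgs1 was higher as well. That call was lost when the values were rescaled to equal totals (adjusted p = 0.085) or equal medians (0.11), and in each run alone, and camera gave an adjusted p of 0.94 with an estimated correlation. Camera called the MAP kinase list (adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.83 with an estimated correlation). In simulated data of this comparison 78.8% of genes changed 2-fold and 40.8% of genes changed 1.5-fold were called, so smaller differences were often not detectable at this number of mice. Those simulations changed more genes at once than passed here, which loosens the adjusted threshold. A gene changed alone would be called less often.

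In COX-2>COX-1 cells Mef2a, a transcription factor of the MEF2 family, was the 1 gene besides Ptgs1 to pass. Its signal was 100.4 ± 43.1 against 263 ± 34.1 in WT+LPS (SD, n = 6 each), 2.80-fold lower, with all 6 samples below all wild-type samples (adjusted p = 0.00031). Within runs 1, 2 and 3 the log2 change was -1.49, -1.88 and -1.09. Limk1 was at 169.9 ± 24.1 against 233 ± 24.1 (adjusted p = 0.13), opposite in sign to its change in COX-1>COX-2, and Mafg, a small MAF protein, at 158 ± 97.9 against 256 ± 34.0 (adjusted p = 0.12). Without COX-2>COX-1 sample 52 Mafg passed, with an adjusted p of 0.0015. The scavenger receptor Cd163 was at 58.6 ± 22.1 against 106 ± 31.4 (adjusted p = 0.19), and the chemokine Ccl7 at 10206 ± 1709 against 7298 ± 1354 (adjusted p = 0.31).

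The count was 0 genes higher and 2 lower of 202, with 26 genes at an unadjusted p under 0.05. It was 2 with run as a block, and within runs 1, 2 and 3 it was 1, 2 and 1. Without a filter on low signal 2 further genes were called, giving 4. None of 16 lists moved on balance in one direction by fry, and the mixed test, which allows either direction, called the eicosanoid list (adjusted p = 1.2e-09; camera adjusted p = 0.67 with an estimated correlation). Its only member past the test was Ptgs1, the exchanged gene itself. No cytokine, chemokine, interferon-stimulated or NF-kB gene passed.

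Reversa cells, with both exchanges, showed the most changes. Besides Ptgs2, the T cell attracting chemokines Ccl5 and Cxcl9 fell, Ccl5 2.31-fold to 18633 ± 4862 (n = 5) from 42109 ± 3926 (n = 6) and Cxcl9 4.36-fold to 770.2 ± 598 from 2808 ± 832 (SD; adjusted p = 0.00051 and 0.0091). Of the type 2 cytokine genes, Il13 was at 41.7 ± 21.2 against 8.36 ± 6.18, at least 1.89-fold higher (adjusted p = 0.00051), and Il5 at 72.0 ± 47.5 against 15.6 ± 13.8, at least 2.69-fold higher (adjusted p = 0.016). Most wild-type samples were under 20 for both genes. The small heat shock protein Hspb1 rose 2.73-fold to 188 ± 104 (adjusted p = 0.016).

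Tlr8 fell 3.21-fold to 210.1 ± 127 from 628 ± 221 (adjusted p = 0.0012) and Tlr6, a partner of Tlr2, fell 1.87-fold (adjusted p = 0.020), and none of the other 14 Toll-like receptors and adaptors passed. The lipid receptor Trem2 fell at least 2.17-fold, to 18.4 ± 11.5 from 54.0 ± 19. The C1q chains C1qa and C1qb fell 1.89-fold and 1.70-fold, to 4007 ± 1347 and 11437 ± 3857, the 2 of 10 complement genes to pass (fry adjusted p = 0.27 for the list). With Trem2 they made 3 of 9 macrophage markers lower, and the other 6 did not pass, among them Alox15 (log2 change -0.41 ± 0.35, SE) and Mrc1 (-0.83 ± 0.29). Retnla, a marker of alternative activation, fell 2.27-fold to 10627 ± 4937 from 23001 ± 8927 (adjusted p = 0.018). Il18rap fell 2.32-fold, Ptger3, a receptor for prostaglandin E2, 2.60-fold, and Plcb1, a phospholipase C, 1.89-fold. Fry found the Toll-like receptor list (adjusted p = 0.021, median -0.38) and the macrophage markers (adjusted p = 0.031, median -0.52) lower on balance, and neither call held under rescaling by 4 reference genes (0.072 each), by medians (0.11 each) or by totals (0.14 and 0.099), or within single runs. Camera with an estimated correlation gave an adjusted p of 0.57 for each.

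Most inflammatory genes did not pass the test in Reversa. None of the 14 pro-inflammatory cytokines passed, with Il6 at 2273 ± 601 against 2061 ± 492 and Il1b at 5315 ± 3084 against 5232 ± 1609.7, and none of the 4 neutrophil-attracting chemokines passed, with Cxcl1 at 6218 ± 2775 against 10775 ± 4022 (adjusted p = 0.17). Of 17 interferon-stimulated genes 1 was lower and 16 did not pass, and none of the 11 NF-kB genes passed. The mixed test called the anti-inflammatory list (adjusted p = 0.00035; Il13 higher, Trem2 and Retnla lower, with a median of -0.08 and a mean of 0.10), the chemokines of monocytes and lymphocytes (0.028; median 0.37, mean -0.14) and the eicosanoid list (0.015), and camera did not (adjusted p = 0.98, 0.98 and 0.91 with an estimated correlation). In the eicosanoid list the members past the test were Ptger3 and Ptgs2, an exchanged gene itself, so its mixed call in part restates the exchange. Of the markers of other cell types, none of 6 T cell and NK cell markers (median -0.41), 3 B cell markers (-0.05) or 3 mesothelial and stromal markers (0.58) passed. Camera called the MAP kinase list and the macrophage markers (adjusted p = 0.010 each), but not with an estimated correlation (adjusted p = 0.75 and 0.57 with an estimated correlation). Adjusted over the list alone, 10 of the 16 lists had the same counts, and 4 macrophage markers were lower in place of 3.

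The count in Reversa was 3 genes higher and 14 lower of 202, and 43 genes had an unadjusted p under 0.05. With run as a block the count was 17, all of them the same genes, and within runs 1, 2 and 3 it was 9, 5 and 9, with 14 of the 17 genes of one sign in all 3 runs. In run 3 alone C1qb, Plcb1 and Tlr6 stood at 0.00, 0.04 and 0.02 on the log2 scale. Other changes also shrank over runs 1, 2 and 3, with Hspb1 at 2.40, 1.32 and 0.18 and C1qa at -1.52, -0.74 and -0.19. Without run 1 all 17 genes kept their direction, but only 10 of them an unadjusted p under 0.05. Without Reversa sample 51 the count was 9, with C1qa, C1qb, Hspb1, Il5, Plcb1, Ptger3, Retnla and Tlr6 past the threshold no longer. On the second principal component of the LPS samples this sample stood at 11.99, and the other Reversa samples at -5.02 to 5.95. Over all 11 fits that left out 1 sample, 8 of the 17 genes kept the call each time. With only the groups of the comparison in the fit the count was 9, and with signal above 20 in all samples required it was 10. Rescaled to equal totals the split was 10 higher and 13 lower, and to equal medians 4 higher and 9 lower. Equal totals moved the median log2 change of all genes by 0.20.

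**Figure D3:**
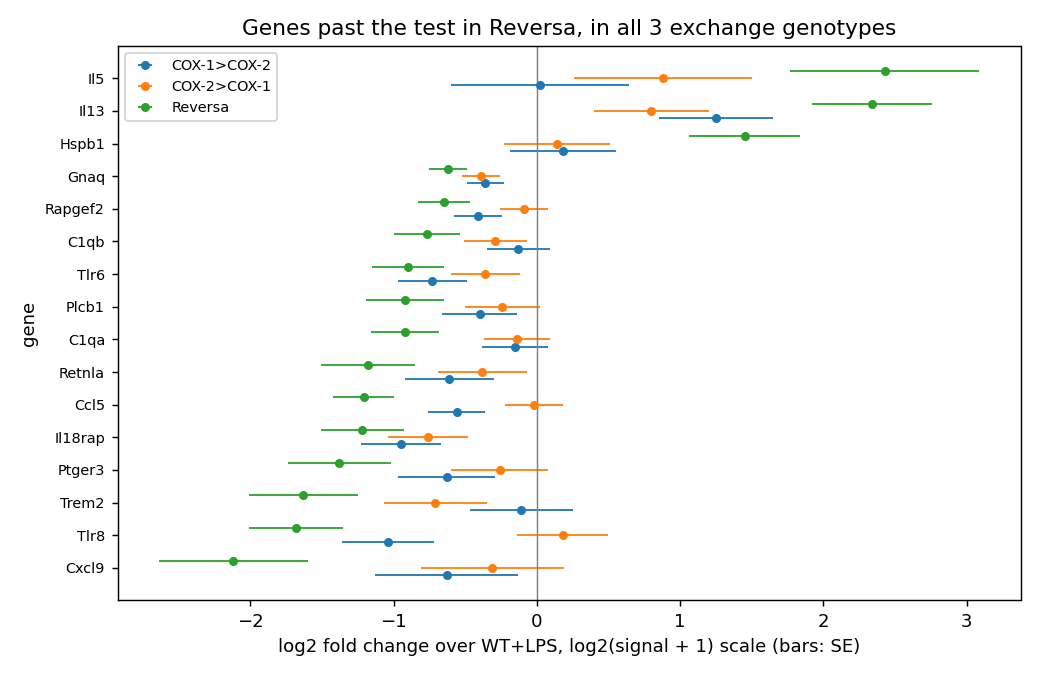
Log2 fold change over WT+LPS, with its SE as bars, of the genes that passed the test in Reversa (Ptgs2 left out), in each of the 3 exchange genotypes. Cxcl9 is at -2.12 and Hspb1 at 1.45 in Reversa, and the points of Il5, Il13 and Trem2 are fitted values of genes with most samples of a group under 20. The points of the single exchanges for the same genes did not pass the test.

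The single exchanges were then set against each other, so that a gene could be tested for a difference between them. Limk1 was 2.14-fold higher in COX-1>COX-2 than in COX-2>COX-1 (adjusted p = 1.6e-06), with log2 differences of 1.45, 0.82 and 1.02 in runs 1, 2 and 3. Mef2a was 2.82-fold higher (279.8 ± 97.1 against 100.4 ± 43.1, adjusted p = 0.00014), with 1.92, 1.97 and 0.60 in the runs. Mafg was 2.58-fold higher at 376 ± 108 against 158 ± 97.9 (adjusted p = 0.00062). Ptgs1 and Ptgs2 differed by at least 21.7-fold and 309-fold, in opposite directions. The interleukin-6 receptor gene Il6ra, the prostacyclin receptor gene Ptgir, Ppp1r12b (at least 1.09-fold, adjusted p = 0.015) and Flt1 were also higher in COX-1>COX-2, and Tlr8, Cd4 and Mx2 lower. Of the 12 fits without 1 sample, Mx2 lost its call in 7, Flt1 in 5, Cd4 in 3 and Ppp1r12b and Tlr8 in 1 each (highest adjusted p = 0.10, 0.093, 0.093, 0.062 and 0.062). Mx2 was also lost with run as a block.

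In all 8 genes were higher and 4 lower in COX-1>COX-2. With run as a block the count was 11, and within runs 1, 2 and 3 it was 2, 7 and 8. It was 26 (24 higher, 2 lower) when rescaled to equal totals, 19 (15 and 4) to equal medians, 13 (11 and 2) by 6 reference genes and 7 without COX-1>COX-2 sample 57. By fry the 11 monocyte and lymphocyte chemokines were lower on balance in COX-1>COX-2 (median -0.53, adjusted p = 0.0061) with no single member past the test, a call lost under rescaling by 6 reference genes (adjusted p = 0.089) and by camera with an estimated correlation (adjusted p = 0.71). Equal totals, equal medians and 6 reference genes moved the median log2 difference of all genes by 0.26, 0.12 and 0.12.

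Reversa differed from COX-1>COX-2 in 3 genes. Csf2 was at least 3.15-fold higher in Reversa (79.5 ± 43.1, n = 5, against 16.5 ± 7.32, n = 6; adjusted p = 0.0017), Ptgs2 at least 12.8-fold higher and Trem2 at least 2.01-fold lower (adjusted p = 0.028). The call of Trem2 was lost in 6 of the 11 fits without 1 sample (highest adjusted p = 0.091), and with only the groups compared (adjusted p = 0.16). Il5 and Arg1 were among the 5 smallest p-values and did not pass. A run block gave 3, and within runs 1, 2 and 3 it was 1, 20 and 10. It fell to 2 without COX-1>COX-2 58, 59 or 60 or Reversa 53, and rose to 13 without Reversa sample 55-56 and to 9 without sample 52, to 6 without Reversa 51, COX-1>COX-2 55 or COX-1>COX-2 33, and to 12 with Reversa 55 and 56 kept apart. Rescaled to equal totals the split was 5 higher and 4 lower, and by 4 reference genes 4 and 1. Ptgs1 was at 240.4 ± 171 in Reversa against 441 ± 84.1 (exact permutation p = 0.035, limma adjusted p = 0.061), and limma called it without Reversa 52 (adjusted p = 0.0017) or without Reversa 55-56 (0.020).

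Against COX-2>COX-1 Reversa cells differed in 22 genes, 11 higher and 11 lower. Mef2a was 3.09-fold higher in Reversa (292 ± 56.7 against 100.4 ± 43.1, adjusted p = 0.00011), and its WT+LPS level was 263 ± 34.1. Tlr8 was 3.63-fold lower and Ccl5 2.27-fold lower (adjusted p = 0.00029 each), and Ptgs1 was at least 10-fold higher and Ptgs2 24.1-fold lower. With run as a block the count was 21, and within runs 1, 2 and 3 it was 4, 12 and 13. It lay between 11 and 25 without single samples, at its lowest without COX-2>COX-1 54. It was 12 to 14 without COX-2>COX-1 52, 53 or 56 or Reversa 52, 53 or 54. Of the 22 genes 8 kept the call in all 11 fits without 1 sample. The count was lower than in any of these fits with only the groups compared or the replicate number as a block. Rescaled to equal totals the split was 24 higher and 5 lower, to equal medians 10 and 4, and by 4 or by 6 reference genes 11 and 5.

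Whether both exchanges add up was tested as the difference between the Reversa change and the sum of the single-exchange changes on the log2 scale. It passed for 4 genes, all above the sum. Ptgs1 lay 5.07 ± 0.44 and Ptgs2 6.49 ± 0.66 (SE) above it, values that depend on the floor of 1 in the single exchanges. Mef2a lay 1.62 ± 0.37 above it (adjusted p = 0.010), with 1.28, 1.85 and 1.53 within the runs. Csf2 lay 2.08 ± 0.55 above it as fitted, with 4 of the 6 COX-1>COX-2 samples under 20 (adjusted p = 0.042), a call lost in 14 of the 23 fits without 1 sample and with run as a block (adjusted p = 0.068), which gave a count of 3.

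All 3 genotype changes share the WT+LPS samples, and this alone makes them correlate. Across 200 genes without Ptgs1 and Ptgs2, which are not independent replicates, the log2 changes of COX-1>COX-2 and Reversa had r = 0.48 where unchanged simulated groups gave 0.47, and a covariance of 0.096 where simulation gave 0.045. For COX-2>COX-1 and Reversa r was 0.43 (simulated 0.47) and the covariance 0.091 (simulated 0.044). For the single exchanges r was 0.09 (simulated 0.51) and the covariance 0.011 (simulated 0.046). With the wild-type samples split 3 and 3 so that no sample was shared, the mean r over 20 splits was 0.34, 0.30 and -0.07. Among called genes 1 was shared in direction, Ptgs2, lower in COX-1>COX-2 and Reversa. Its native gene is replaced in both genotypes, so this shared call is set by the exchange. At an unadjusted p under 0.05, COX-1>COX-2 and Reversa shared 2 genes higher and 9 lower, Ptgs2 among them (simulated 0.80 and 1.03). COX-2>COX-1 and Reversa shared 2 and 3 (simulated 0.82 and 0.98), and the single exchanges 0 and 2 (2.16 together in simulation). Independent lists as long as the real ones give 0.52 and 1.52, 0.67 and 2.36, and 0.31 and 0.93, in the same order. The simulated groups held no changed genes and the independent lists no shared controls, so chance can give more than either.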

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

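The tests of cell shares, of runs, of linked variants and of the scaling of genes changed at least 2-fold were chosen only after the result was seen, while the splits of samples, the scaling test over all called genes and the test of single Reversa samples were set out beforehand. Within groups, 8 of 179 sets of gene values and 2 of 15 sets of lane measures held a sample far from the others, where chance gives about 5% of sets. Among vehicle samples, Jun stood at 537 in sample 38 (others 232 to 332), and the recovered total was 717094 counts in sample 41 (others 298396 to 440555). In WT+LPS, sample 54 stood apart in Jun (1934, others 1292 to 1474) and Max (855, others 695 to 746), sample 55 in Csf2 (61.7, others 25.3 to 37.7) and Mafg (321, others 225 to 256), sample 56 in Cd40 (2796, others 3385 to 3728), and sample 51 in total signal (766533, others 620696 to 652455). COX-2>COX-1 sample 52 stood apart in Hsh2d (982, others 502 to 599.9) and Mafg (346, others 74.3 to 161).

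Reversa differed from the sum of the single exchanges by 6.49 on the log2 scale for Ptgs2, 5.07 for Ptgs1, 1.62 for Mef2a and 2.08 for Csf2, each by the test of the difference itself. The values for Ptgs2 and Ptgs1 are set by the exchange and by the floor of 1, since the single exchange without each transcript lay under 20. Most COX-1>COX-2 samples were under 20 for Csf2, and its call was lost in 14 of the 23 fits without 1 sample. Genes left out for low signal held 2 that were above background in an LPS group and in no vehicle sample. Il9, a type 2 cytokine, reached 30.5 in Reversa and was above 20 in 4 of 5 samples there, and Ifna1, a member of a family of near-identical genes, reached 44.1 in COX-2>COX-1 and was above 20 in 5 of 6.

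The first pattern is the split of the LPS response into 100 genes higher and 69 lower, set against the authors' scaling and against a loss of resident macrophages. Of the 169 genes 69.2% kept direction and call under all 4 other scalings, which leaves open for the others whether their call comes from the scaling. Of the 120 genes changed at least 2-fold 95.0% kept both, which decides nothing, since the scalings moved the median of all genes by at most 0.91 and such genes were chosen for a change of 1 or more on the log2 scale. All 9 macrophage markers lay below 0, and 7 passed the test, by unequal amounts from -0.52 for Tlr4 to -3.05 for Alox15. The changes of all 9 had a spread of 3.27 times their median SE, which argues against a smaller share of macrophages as the whole cause. The limit of 3 was chosen after the result was seen, and the spread passes it only with Alox15, the marker furthest from the others. A change in gene expression after LPS and a partial change in the cells harvested both stay open.

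The second pattern is the set of 17 genes called in Reversa, with Il5, Il13 and Hspb1 higher and Ccl5, Cxcl9 and Tlr8 among those lower. The 9 T, NK and B cell markers had a median log2 change of -0.28 (-0.54 to -0.06 without single Reversa samples) and ran from -0.94 to 0.12 with none past the test, so more lymphocytes in the harvests, as a source of Il5 and Il13, stay open. All 9 macrophage markers lay below 0, with a spread of 1.62 times their median SE, wider than the 1 of a shared fall and under the 3 set for unequal changes, so fewer macrophages in the Reversa harvests cannot be told apart from lower expression. Without any single Reversa sample 100% of the genes kept direction and an unadjusted p under 0.05, which argues against 1 aberrant sample as the whole cause, although the count of adjusted calls fell to 9 without sample 51, and without run 1 only 58.8% kept both. A change that differs between the runs therefore stays open, as do the cell shares, the lane position and an effect of the exchanged genes.

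The third pattern is Mef2a, low in COX-2>COX-1 alone of the 3 genotypes, and Limk1, with opposite signs in the single exchanges. The difference between the single exchanges was at least 3.42 times its SE within each run for Limk1, which argues against the runs. For Mef2a it was 1.64 times its SE in run 3. Each run held both groups, and with run as a block the Mef2a difference was 1.49 ± 0.24 (SE). A run effect that both groups share therefore does not account for it, but a difference in its size between the runs stays open. Neither gene was among the 200 nearest genes on each side of Ptgs1 or Ptgs2 in the reference (0 of 2). This argues against a variant near the exchanged loci that lies in or beside these genes. A linked variant that acts on distant genes was not tested. Mef2a stood 1.62 above the sum of the single exchanges in Reversa, which carries the same exchange. An unlinked variant of the COX-2>COX-1 line was not tested and may account for Mef2a as well as the genotype may, with a change that kept its call in all 12 fits without 1 sample.

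Chance was tested with 100 splits of the same samples per comparison, the real one included. As many genes came up in 1 split for LPS (169, highest other 136), 4 for COX-1>COX-2 (2, highest other 3) and 2 for COX-2>COX-1 (2, highest other 3). They came up in 2 for Reversa (17, highest other 28) and 1 between the single exchanges (12, highest other 5). For Reversa against COX-2>COX-1 it was 2 (22, highest other 33) and for the departure from the sum 3 (4, highest other 25). Counts as high thus came up in a share of splits under 0.05 in these comparisons, without a correction over them. For LPS, where no gene is exchanged, chance can thus be excluded for the count. All the other counts include 1 or both exchanged genes, so their splits in part restate the genotype. For the single exchanges and the departure from the sum they do not exclude chance for the other genes. In both comparisons of Reversa given here, another split gave more genes than the real one. Without sample 58 the count for COX-1>COX-2 was 1. For Reversa against COX-1>COX-2 as many genes came up in 19 splits (3, highest other 47), so chance cannot be excluded for the count. Splits with several times the real count, as there and in the departure from the sum, point to a structure of the samples, whose source was not tested.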

How the results depend on the processing

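Run as a block, each run alone, Reversa 55 and 56 kept apart and the prior variance that follows the mean were chosen only after the data were seen, and the other alternatives before. Of 3715 values of named genes under an alternative, 3534 kept direction and side of the threshold, 143 lost the call, 34 gained it and 4 changed sign. The sign changes were values near 0, with Birc2 after LPS at 0.00 under equal medians, and in run 3 alone C1qb at 0.00, Plcb1 at 0.04 and Tlr6 at 0.02 in Reversa. The cause was not tested, except that fewer genes or samples leave less to call. TMM scaling, median-ratio size factors, a count-based Wald test and the subtraction of background from raw counts were not run, since the values are not counts and already have a background removed. The other deposited table holds equal values. Depth limits the lowest genes, where a single count is worth up to 1.937 signal units.

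Counts of called genes moved as follows. Between the single exchanges there were 26 genes under equal totals, 19 under equal medians, 7 with signal above 20 in all samples and 22 with only the groups compared. For Reversa against COX-1>COX-2 there were 9 under equal totals, 5 by 4 reference genes, 0 with signal above 20 in all samples, 11 with a pseudocount of 10, 1 with only the groups compared and 12 with Reversa 55 and 56 apart. For Reversa against COX-2>COX-1 there were 14 under equal medians, 14 without a filter, 11 with signal above 20 in all samples and 9 with only the groups compared. Reversa against WT+LPS gave 10 with signal above 20 in all samples and 9 with only the groups compared. COX-1>COX-2 gave 1 and COX-2>COX-1 gave 1 with signal above 20 in all samples, where the departure from the sum gave 1, and COX-2>COX-1 gave 4 without a filter. Ptgs1 in COX-1>COX-2 passed with only the groups compared (0.92, adjusted p = 0.049).

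Within runs 1, 2 and 3 the counts were 111, 143 and 152 for LPS, 1, 1 and 1 for COX-1>COX-2, 1, 2 and 1 for COX-2>COX-1, 9, 5 and 9 for Reversa, 2, 7 and 8 between the single exchanges, 1, 20 and 10 for Reversa against COX-1>COX-2, 4, 12 and 13 for Reversa against COX-2>COX-1 and 1, 1 and 4 for the departure from the sum. Ptgs2 in Reversa did not pass in run 2 alone (-3.40, adjusted p = 0.13).

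Without single samples the counts ranged from 163 to 167 for LPS, 1 to 5 for COX-1>COX-2, 2 to 3 for COX-2>COX-1, 9 to 23 for Reversa, 7 to 12 between the single exchanges, 2 to 13 for Reversa against COX-1>COX-2, 11 to 25 for Reversa against COX-2>COX-1 and 3 to 6 for the departure from the sum. Lists called by fry then ranged from 0 to 2 for COX-1>COX-2, 0 to 4 for Reversa, 1 to 2 between the single exchanges, 0 to 3 for Reversa against COX-2>COX-1 and 0 to 1 for the departure from the sum. Genes shared by COX-1>COX-2 and Reversa ranged from 1 to 2.

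Lists called by fry moved with the settings too. For COX-1>COX-2 the count of 1 list fell to 0 under equal totals, under equal medians, without a filter, with signal above 20 in all samples and in runs 1, 2 and 3 alone. For COX-2>COX-1 it was 2 under equal totals, 1 by 6 reference genes and 1 with only the groups compared. For Reversa it was 0 under equal totals, by 4 reference genes, under equal medians and in each run alone, and 1 with signal above 20 in all samples, with only the groups compared and with Reversa 55 and 56 apart. Between the single exchanges it was 2 under equal totals, 0 by 6 reference genes, 2 under equal medians, 3 with only the groups compared and 0 in runs 2 and 3 alone. For Reversa against COX-2>COX-1 it was 3 under equal totals and 1 with Reversa 55 and 56 apart, for Reversa against COX-1>COX-2 it was 1 without a filter, and for the departure from the sum it was 1 under equal totals. Genes called in the same direction numbered 1 for COX-2>COX-1 and Reversa under equal totals, and 0 for COX-1>COX-2 and Reversa with signal above 20 in all samples and in run 2 alone. At an unadjusted p under 0.05 they numbered 2 for the single exchanges, 11 for COX-1>COX-2 and Reversa and 5 for COX-2>COX-1 and Reversa. Unchanged groups simulated with the same controls gave 2.16, 1.83 and 1.80, but they held no changed genes, so chance can give more between the real lists.

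The replicate numbers 51 to 56 recur in WT+LPS, COX-2>COX-1 and Reversa. Only 4 of 16 pairs of same-numbered samples had a correlation of deviations over 0.1 (range -0.37 to 0.23). Of 17 samples 2 correlated best with their own number, so the deviations gave no sign of a pairing by number. Same-numbered samples of these groups were also measured in the same run, so a block of replicate numbers takes up the run as well. With the replicate number as a block, Reversa against COX-2>COX-1 gave 10 genes and 2 lists, and Reversa against WT+LPS gave 12 genes and 0 lists.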

Other observations

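The tests are those of the same limma fits, and the genes they are given for were chosen only after their values were seen. Il17a, a cytokine of type 17 responses, had a Reversa signal of 90.6 and 349 in run 1 (samples 52 and 51), 2283 and 4446 in run 2 (samples 53 and 54), and 8615 and 8653 in run 3 (the near-identical samples 55 and 56), against 225 to 602 in WT+LPS and under 20 in all vehicle samples. The mean of 3161 ± 3525 (SD, n = 5) did not pass the test against 414 ± 158 (n = 6; limma adjusted p = 0.17). The log2 change of Il17a within runs 1, 2 and 3 was -0.79, 3.10 and 4.09. In the same runs it was -0.06, -1.12 and -0.76 in COX-1>COX-2 and 1.31, 0.95 and 0.51 in COX-2>COX-1, so a difference between runs that all groups share does not account for the order in Reversa. What sets the Reversa mice of each run apart was not tested. Il22 ran from 159 to 4859 in Reversa. The changes of Il13 and Il5 shrank over the same runs, with fitted values of 3.88, 1.84 and 0.83 for Il13 and 3.92, 2.32 and 0.45 for Il5. Arg1, an enzyme of alternative activation, was at 6026 ± 3481 in Reversa and 2717 ± 1183 in WT+LPS (adjusted p = 0.27), and Ccl22 at 2525 ± 975 and 1229 ± 252 (adjusted p = 0.11).

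Set beside the LPS response, the 14 genes lower in Reversa held 6 that LPS raises in wild-type cells (Ccl5, Cxcl9, Il18rap, Ptger3, Ptgs2 and Rapgef2), 7 that it lowers (C1qa, C1qb, Gnaq, Plcb1, Retnla, Tlr8 and Trem2) and 1 that did not pass after LPS (Tlr6). Of these, Gnaq, Plcb1, Rapgef2 and Tlr8 did not keep their LPS call under all 4 other scalings. Of the 3 genes higher in Reversa, Il5 and Il13 were mostly under 20 in both wild-type groups. Hspb1 passed after LPS (adjusted p = 0.039), but not in 6 of the 12 fits without 1 sample, and it stood at -0.06 under equal medians. Both comparisons use the same WT+LPS samples with opposite signs, so chance alone favours opposite directions.

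Pla2g4a, the cytosolic phospholipase A2 that releases arachidonic acid, lies 3 genes from Ptgs2 in the reference gene order. Its log2 change against WT+LPS was -0.28 ± 0.23 (SE) in COX-1>COX-2, -0.08 ± 0.23 in COX-2>COX-1 and -0.55 ± 0.24 in Reversa, and none passed the test (adjusted p = 0.69, 0.94 and 0.17). LPS raised it 4.39-fold in wild-type cells. Ppp1r12b lies 154 genes from Ptgs2. Its signal was 23.1 ± 8.18 in COX-1>COX-2, 9.70 ± 3.02 in COX-2>COX-1 and 23.8 ± 14.8 in Reversa (SD; n = 6, 6 and 5), against 20.5 ± 6.79 in WT+LPS, and no change against WT+LPS passed (adjusted p = 0.89, 0.12 and 0.92). It was lower in COX-2>COX-1, whose exchanged gene is Ptgs1, than in COX-1>COX-2 and Reversa (adjusted p = 0.015 and 0.032), calls lost in 1 of 12 and in 7 of 11 fits without 1 sample.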
